A study of Mus musculus with 127 samples.

How the data were processed

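Single F123 mouse embryonic stem cells, freed of feeder cells by passaging, were cut into serial nuclear profiles, and the DNA of each profile was amplified as a whole genome and sequenced on an Illumina HiSeq X, per the labels' protocols. The submitters' processing notes name Trim Galore 0.6.4, Bowtie2 2.3.5, Picard (with no version) and the mm10 build. How reads became 1 position per window, what file 0 and file 1 of a cell stand for, and how windows seen in several profiles were treated are not given in the sources used here. Each deposited file lists 10 kb windows with a chromosome, a start, an end and a position along the slicing axis, per the file headers, and the authors' unit of that position is another unit than a count, with no name in the headers. It carries no read count, so the read depth behind a window is unknown. The number of located windows stands for depth here and gives the precision of a position only indirectly.

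The 20 files were read as deposited. The group of each profile was its cell, taken from the labels, and the batch (B16F or B18F) came from the title prefix. Profiles of a cell are serial slices of 1 nucleus and not replicates, so each cell gave 1 value to a test. Nothing in the labels says that the cells of a batch came from separate cultures, so p-values measure the spread between these cells. The 5 controls have no file of positions and entered no test. Every window had 1 position, no file repeated a window, so the test set beforehand of whether neighbouring positions share loci was not possible.

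Windows on the 19 autosomes and X were averaged into 1 Mb bins per file. Distance is the absolute difference of 2 bins' positions. Distances were averaged at separations of 1, 2, 5, 10, 20, 50 and 100 Mb within a chromosome and file, and over pairs of bins of the same and of different autosomes. File agreement compared the same bin in file 0 and file 1 with bins of different autosomes across the files. Distance from the midpoint of the cell's lowest and highest position was ranked over all bins of the cell as a percentile, and percentiles were averaged over bins and files. Chromosome lengths were taken as the end of the last located window. Gene positions came from the RefSeq gene table of assembly GRCm38.p6, whose primary coordinates are those of mm10, with 21627 protein-coding genes among the 49550 genes on the autosomes and X. Gene coordinates are 1-based. The 11 gene lists hold 2305 matched genes without pseudogenes, and a gene's bin is the bin of its midpoint. Family prefixes were narrowed by pattern to leave out unrelated genes, although the keratin prefix still took in Krtdap. A list's shift is the mean percentile of its bins minus that of all gene-holding bins of the same chromosomes.

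Windows in both files were compared with the number expected if the files were independent, the product of the 2 files' windows divided by the length of the chromosomes in windows. Runs are stretches of windows listed in 1 file only that stay in the same file. Positions were taken as identical within 1e-06 axis units.

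Values per cell were tested against 0 with an exact sign-flip permutation test over 1024 sign patterns, where 10 cells cannot give a p under 0.00195, 6 cells not under 0.0312 and 4 cells not under 0.125. Batches were compared with an exact permutation test over 210 splits. The similarity of chromosome positions between cells was tested with 100000 permutations. Benjamini-Hochberg adjustment was made over the 9 position results, over the 11 lists, over the 20 chromosomes and over the 7 separations. The tests, lists, chromosome sets and most alternative settings were fixed before the data were examined. Genes were named by a rule fixed then: Pou5f1, Nanog, Sox2, Klf4, Esrrb and Zfp42, and in each list the 2 members with the lowest and the 2 with the highest mean percentile among those located in at least 6 cells. The rule gave no order for ties, which were taken alphabetically. Not every gene that the rule picks is printed. Chromosomes were named if they belong to a set or are among the 3 nearest to or the 3 farthest from the midpoint in mean percentile.

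The settings fixed beforehand were 250 kb bins, at least 5 windows per bin, the median position of a bin, the outermost positions left out, each file alone, the median as centre, the distance as a percent of that of the farthest position, gene density within chromosomes, all gene-holding bins as background, separations up to 20 Mb, distinct 1 Mb bins in place of windows, X against each autosome, each batch alone and each cell left out. Alternatives chosen after seeing the data were the percentile of single windows, shared windows left out, 1 window drawn per bin (mean of 10 draws) and the mean over 20 shuffles of positions within each file subtracted.

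The computation was tested on simulated data made by shuffling positions among the 1222168 windows, with 20 runs per setting. With nothing planted, 41 of 200 tests had p under 0.05, and 32 of these came from 2 results, the chromosome ends (20 of 20 runs) and the slope on separation (12 of 20 runs, with a mean slope of 0.004). Leaving these out, 9 of 160 tests were called, 4 of them for gene density (mean correlation −0.011). Bins averaged over more windows vary less, and with 1 window drawn per bin 17 of 200 tests were called. Planted chromosome offsets, a planted list, chromosomes planted near the midpoint and copied positions between the files were each recovered in 20 of 20 runs by the test meant for them. The planted list moved by −15.3 points and the planted chromosomes differed by 4.83 points. The offsets gave 1.09 and the copies −0.06 on the log2 scale. Smaller effects were not planted, so whether these tests would find them is unknown. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.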

Results

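Sequential genome architecture mapping cuts single nuclei into serial slices, called nuclear profiles, and sequences the DNA of each slice, so that a stretch of genome can be placed along the cutting axis of the nucleus. The series applied it to F123 cells, a mouse embryonic stem cell line from a CAST x 129 hybrid embryo whose parental genomes differ by many sequence variants. The samples were 122 profiles of 10 cells, 1 negative control and 4 positive controls. Batch B16F gave 4 cells (Cell17 with 23 profiles, Cell18 with 16, Cell19 and Cell20 with 12 each), and batch B18F gave 6 cells (Cell25 with 15, Cell26 with 7, Cell27 and Cell28 with 8 each, Cell38 with 10 and Cell39 with 11). Each cell had 2 files of positions, numbered 0 and 1, in which every located 10 kb window of the mm10 genome had 1 position on the axis. The axis unit is not named in the files, so distances are given in axis units. The cell is the unit of replication throughout, and all sign-flip and permutation tests are two-sided.

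The 10 cells located 1222168 windows in all, with a median of 123899 per cell (both files added) and a range from 56975 in Cell39 to 190076 in Cell25. A file covered between 7.99% (file 0 of Cell20) and 38.1% (file 1 of Cell25) of the autosomal windows. Cells of batch B18F had 128879 ± 46805 windows (SD, n = 6) and cells of batch B16F had 112223 ± 26934 (SD, n = 4), although B16F cells were cut into more profiles (15.75 against 9.83 on average, exact permutation p = 0.0333). The difference in windows was within the spread between cells (B18F minus B16F, 0.13 on the log2 scale, exact permutation p = 0.724 over 210 splits). The files hold no read counts, so the read depth behind a window is unknown here.

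The number of windows differed widely between positions along the axis. Positions fell on a grid with a step of 0.2 axis units, with 1 grid position per profile in 8 cells and 1 more than the number of profiles in Cell18 (17) and Cell38 (11). Between 62.8% and 88.1% of the windows of a file lay on the grid, and the rest lay between grid positions. The fullest position of a cell held from 4.17 times (Cell19) to 89.2 times (Cell18) the windows of its emptiest position. Cell18 has 1 position more than profiles, so its emptiest position, with 131 windows, may have no slice behind it. Among the cells with 1 position per profile, the highest ratio was 61.8 in Cell39. Windows between grid positions are not counted here. In Cell39, 2 of 11 positions held 83.3% of the windows on the grid, against 18.2% for equal slices. In Cell19, the 2 fullest of 12 positions held 25.9%, against 16.7% for equal slices. The sampled span of the axis ran from 1.2 axis units in Cell26 to 4.4 in Cell17, so the midpoint of the sampled span need not be the middle of the nucleus.

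**Figure D1:**
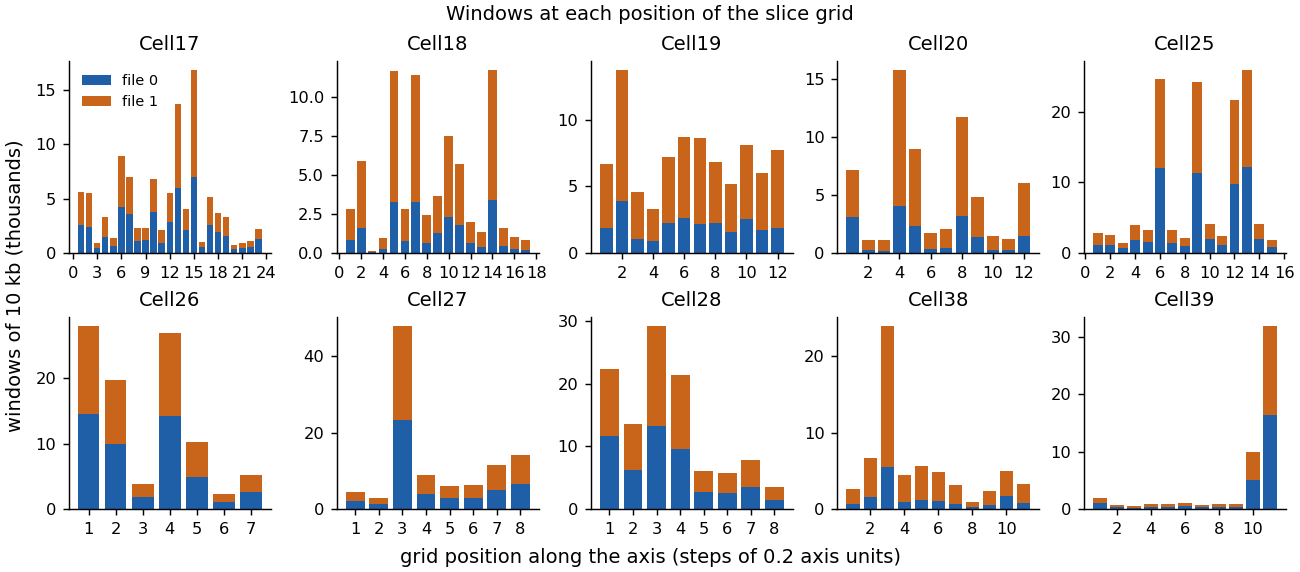
Windows of 10 kb at each grid position along the cutting axis (steps of 0.2 axis units), stacked by file, 1 panel per cell with its own vertical scale. In Cell39 the last 2 positions hold 83.3% of the windows, and in Cell19 the windows are spread most evenly.

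The 2 files of a cell were unequal in size. File 1 listed more windows than file 0 in 8 of 10 cells, by 0.70 ± 0.77 on the log2 scale (SD, n = 10, exact sign-flip p = 0.00977). The ratio was 3.45 in Cell38, 3.08 in Cell20, 2.92 in Cell19 and 2.57 in Cell18, while Cell26 (0.958) and Cell39 (0.956) went slightly the other way. In batch B18F alone the difference was 0.39 with an exact sign-flip p = 0.125. Counted in distinct 1 Mb bins, the difference was only 0.05 (exact sign-flip p = 0.0312), as both files reach most bins. The files do not say which parental copy, if any, a file number stands for.

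X chromosome windows were present in both files of every cell, and few X windows were in both at once, from 0.0699% of them in Cell38 to 5.16% in Cell20. File 1 held 63.7% ± 14.6 of the X windows and 60.96% ± 11.9 of the autosomal windows (SD, n = 10). The share was higher on X by 2.70 ± 3.46 percentage points (higher in 8 of 10 cells, exact sign-flip p = 0.0332). This difference was 4.88 points in the B16F cells and 1.24 points in the B18F cells, where it did not pass (exact sign-flip p = 0.0938). It also missed the threshold when any of 7 cells was left out (highest p = 0.0664), and it was −0.70 points against chromosome 1 alone, so it is not a stable difference.

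Sharing of windows between the files set X apart from the autosomes. On the autosomes, the number of windows listed in both files was 1.69 ± 0.36 times (SD, n = 10) the number that independent files of those sizes would share, from 1.29 in Cell17 to 2.50 in Cell20. On X the same ratio was 0.239 ± 0.291 and ranged from 0.0136 in Cell18 (8 shared windows against 587 expected) to 0.950 in Cell20. The log2 ratio was lower on X than on autosomes in 10 of 10 cells, by 3.91 ± 1.88 (exact sign-flip p = 0.00195, the smallest that 10 cells allow). On Y, which was not tested on this ratio, it was 0.358 ± 0.578, with Cell20 again the highest at 1.88.

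File membership ran in blocks along the chromosomes. Of adjacent X windows that were each listed in a single file, 94.4% ± 5.64 (SD, n = 10) were in the same file, against 58.1% ± 10.4 from the sizes of the files, an excess of 36.3 points seen in 10 of 10 cells (exact sign-flip p = 0.00195). On autosomes the excess was 32.4 ± 10.1 points and on Y it was 37.1 ± 8.66 points, each in 10 of 10 cells with the same p. The X of Cell18 fell into 67 runs of single-file windows, the longest 32.96 Mb, where windows assigned at random would give 2614 runs. The X of Cell17 fell into 206 runs with a longest run of 15.2 Mb. In Cell27, runs were short, with 1738 on X and a longest run of 1.07 Mb.

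**Figure D2:**
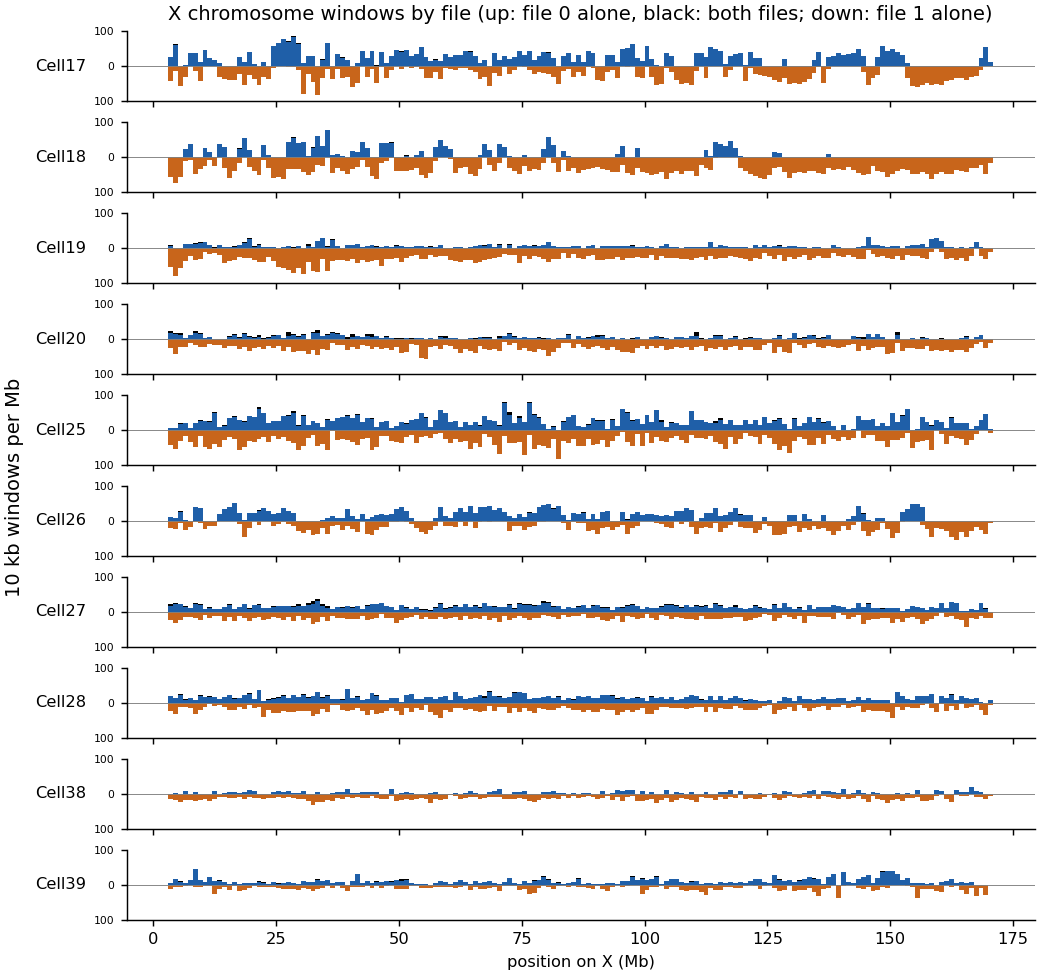
Number of 10 kb windows per Mb along the X chromosome in each cell, upward for windows in file 0 alone (with windows in both files in black on top) and downward for windows in file 1 alone. Windows change file in long blocks in Cell17 and Cell18, whose longest runs are 15.2 Mb and 32.96 Mb, and in short runs in Cell27.

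Megabases that are close on a chromosome lay close along the axis. Autosomal 1 Mb bins separated by 1 Mb were 0.740 ± 0.090 times (SD, n = 10) as far apart as bins of different chromosomes in the same cell and file. The ratio was 0.820 at 2 Mb, 0.876 at 5 Mb, 0.900 at 10 Mb, 0.890 at 20 Mb, 0.934 at 50 Mb and 0.960 ± 0.035 at 100 Mb, and at each of the 7 separations all 10 cells were under 1 (exact sign-flip p = 0.00195 each, adjusted p = 0.00195). The slope of log distance on log separation was 0.050 ± 0.022 and positive in 10 of 10 cells (exact sign-flip p = 0.00195, adjusted over 9 position results p = 0.00586). The Spearman correlation over the 7 separations ranged from 0.75 in Cell20 to 1 in Cell18, Cell25 and Cell27.

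**Figure D3:**
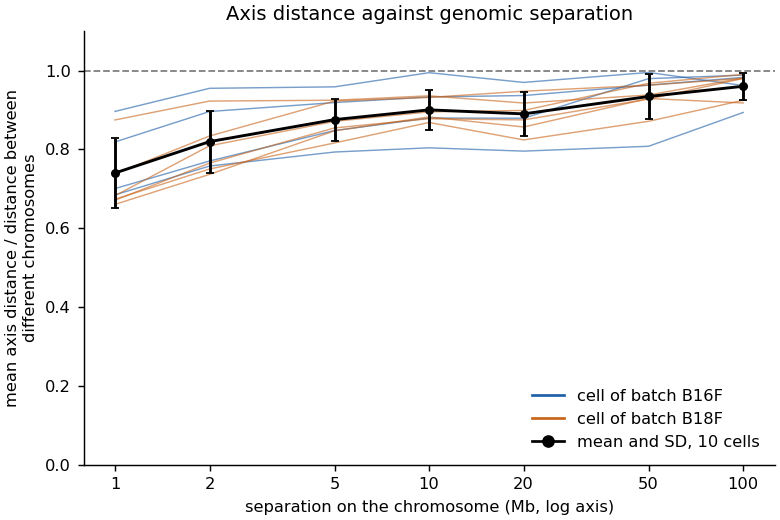
Mean axis distance between 1 Mb bins of the same autosome and file, divided by that between different autosomes, against their separation in Mb (log axis). Thin lines are cells coloured by batch, points and bars are the mean and SD of 10 cells, and every cell lies under 1 (dashed) at every separation.

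Bins of the same autosome were also closer than bins of different autosomes over all separations. The distance between different autosomes was 0.12 ± 0.08 higher on the log2 scale (SD, n = 10), a factor of 1.09, in 10 of 10 cells (exact sign-flip p = 0.00195, adjusted p = 0.00586). The factor was 1.23 in Cell17, 1.149 in Cell39 and 1.02 in Cell20. With positions shuffled among the windows of each file, the mean fell to 0.0023 on the log2 scale. Averaging windows into bins enlarges the contrast: with 1 window drawn per bin, a setting added after the data were seen, the difference was 0.03, a factor of 1.02, still in 10 of 10 cells, and the slope was 0.013.

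The 2 files of a cell placed the same megabase at similar positions. The distance between the files at the same autosomal bin was compared with that between different autosomes across the files. The log2 ratio was −0.63 ± 0.34 (SD, n = 10), a factor of 0.648, and was below 0 in 10 of 10 cells (exact sign-flip p = 0.00195, adjusted p = 0.00586). The contrast was largest in Cell25, where different autosomes were 1.98 times as far apart, and smallest in Cell20 at 1.06 times. Among autosomal windows listed in both files, 49.2% ± 15.5 had identical positions (within 1e-06 axis units), against 12.4% ± 8.29 after shuffling. Leaving out every window listed in both files, a setting added after the data were seen, brought the contrast to −0.22 ± 0.21 (below 0 in 8 of 10 cells, exact sign-flip p = 0.00781). With 1 window drawn per bin it was −0.16.

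Chromosomes were located unevenly, and each cell had its own over- and under-covered chromosomes. Chromosome 12 had 1.73 times the autosomal window density in Cell39 and chromosome 18 had 1.68 times in Cell18, while X had 0.444 times in Cell38. Chromosome 14 had 1.64 times in its highest cell, Cell28, and 1.16 ± 0.25 times over the 10 cells (SD). X had 0.807 ± 0.235 times (below 1 in 8 of 10 cells, exact sign-flip p = 0.0273), which did not pass after adjustment over the 20 chromosomes (adjusted p = 0.326), and no autosome passed. X was above the autosomal density in Cell18 (1.24) and Cell20 (1.04). F123 is a male line as background, with X in 1 copy, so the autosomal density is not what copy number predicts for X. No test was made against that prediction. Chromosome 19, the shortest autosome, had 0.877 ± 0.226 times and chromosome 17, which carries the major histocompatibility complex, had 1.08 ± 0.11 times.

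Mean positions of autosomes within a cell spanned from 6.57% (Cell20) to 24.7% (Cell39) of the sampled axis. Chromosome 5 lay lowest and chromosome 12 highest in Cell17, 0.817 axis units apart, and chromosome 12 lay lowest and chromosome 4 highest in Cell39. Chromosome 6 was lowest in Cell25, Cell26 and Cell27, with chromosome 11 highest in Cell25 and Cell26, although the direction of the axis need not be the same in different nuclei. The order of autosomes in the 2 files of a cell had Spearman correlations across the 19 autosomes from 0.747 in Cell17 to 0.965 in Cell39. Windows listed in both files add to this. Without them, a setting added after the data were seen, the correlation was 0.583 ± 0.252 (SD, n = 10, above 0 in 10 of 10 cells, exact sign-flip p = 0.00195). It ranged from 0.081 in Cell25 to 0.944 in Cell39, against a mean of −0.003 with shuffled positions. Cell18 (0.572), Cell20 (0.291), Cell25 and Cell26 (0.451) lay under the highest shuffled value of their own cell (0.653, 0.640, 0.428 and 0.486). The other cells lay above theirs.

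No chromosome kept the same distance from the midpoint of the sampled axis in all cells. Distance was ranked as a percentile over all bins of a cell, with 0 at the midpoint and 100 at the outermost bin. Chromosomes 3 (45.8 ± 4.61), 8 (45.9 ± 11.4) and 13 (47.1 ± 5.30) had the lowest mean percentiles, and chromosomes 15 (55.2 ± 7.66), 9 (53.7 ± 5.49) and 5 (53.1 ± 9.19) the highest (SD, n = 10). Chromosome 3 (exact sign-flip p = 0.0156) and chromosome 15 (p = 0.0449, exact sign-flip) were under 0.05 before adjustment and neither passed after it (adjusted p = 0.312 and 0.391). The mean rank correlation of chromosome percentiles over the 45 pairs of cells was 0.024 (permutation p = 0.488, 100000 resamples). Chromosome length had no relation past the threshold to this percentile (mean Spearman correlation −0.050 ± 0.166, exact sign-flip p = 0.363) or to the spread of a chromosome along the axis (0.051 ± 0.199, exact sign-flip p = 0.441). For the spread, shuffled positions gave 0.090, and with each cell's shuffled mean subtracted the value was −0.04 (exact sign-flip p = 0.453). Without the outermost positions the spread gave 0.12 (unadjusted exact sign-flip p = 0.0352).

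**Figure D4:**
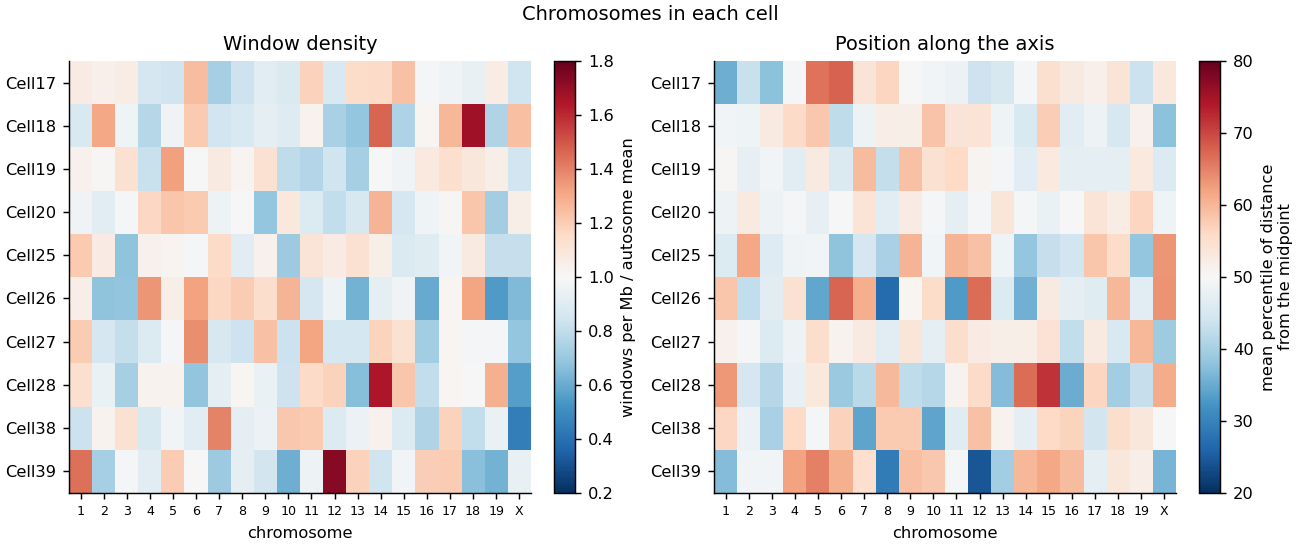
Window density of each chromosome relative to the autosomal mean of the cell (left) and mean percentile of distance from the midpoint of the sampled axis (right), with cells in rows and chromosomes in columns. Chromosome 12 of Cell39 has both the highest density, 1.73, and the lowest percentile, 24.3.

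Gene-rich chromosomes did not lie closer to the midpoint of the sampled axis than gene-poor ones. Positions are given along the cutting axis only and not within a slice, so placement between the centre and the rim of the nucleus was not tested. Among the gene-rich set, chromosome 7 had a mean percentile of 50.6 ± 8.23, chromosome 11 of 50.1 ± 7.41, chromosome 17 of 50.6 ± 4.64 and chromosome 19 of 49.8 ± 6.72. In the gene-poor set, chromosomes 3 and 13 were among the lowest (above), chromosome 14 had 49.1 ± 9.18 and chromosome 18 had 50.7 ± 6.17. The gene-poor set minus the gene-rich set was −2.08 ± 2.92 points (SD, n = 10), negative in 8 of 10 cells, at an exact sign-flip p = 0.0527 (adjusted p = 0.119). Other settings moved this difference both ways, with unadjusted exact sign-flip p throughout. It was −3.98 points with the median position as centre (p = 0.00391), −1.91 with distance scaled to the farthest position (p = 0.0137), −1.44 with 250 kb bins (p = 0.0469) and −2.73 without Cell38 (p = 0.00781). It was −1.33 without the outermost positions (p = 0.232), −1.17 with 1 window drawn per bin (p = 0.0938) and −0.92 with single-window percentiles (p = 0.186). In the B18F cells alone it was −1.30 (p = 0.4375), and in the B16F cells alone, where no test can pass, it was −3.25.

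Whether centromere-proximal chromosome ends lay closer together or farther apart than the opposite ends depended on the setting. Mouse chromosomes carry the centromere at the start of the sequence, and the first 10 Mb of different autosomes, counted from 3 Mb where sequence begins, were compared with their last 10 Mb. The log2 ratio of the mean distances was 0.03 ± 0.18 (positive in 6 of 10 cells, exact sign-flip p = 0.582), which cannot be read against 0, since shuffled positions gave −0.19 and were called in 20 of 20 shuffles. Subtracting each cell's shuffled mean gave 0.22 (exact sign-flip p = 0.00195), whereas 1 window per bin, which removes the bias, gave −0.01 (exact sign-flip p = 0.904), and both settings were added after the data were seen.

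Chromosomes 12, 15, 16, 18 and 19 carry ribosomal DNA arrays, the nucleolar organisers, in many mouse strains. The distance between their first 10 Mb did not differ past the threshold from that of other pairs of autosomes (log2 ratio −0.08 ± 0.20, negative in 5 of 10 cells, exact sign-flip p = 0.242). The ratio was −0.13 with file 0 alone (unadjusted exact sign-flip p = 0.0469) and 0.006 without the outermost positions (exact sign-flip p = 0.898). Over the whole chromosome, chromosome 12 had a mean percentile of 51.5 ± 11.4 and chromosome 16 of 48.2 ± 7.03, and the set as a whole had 51.1 ± 2.45 (SD, n = 10).

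Gene density along the chromosomes did not follow distance from the midpoint. The mean Spearman correlation over autosomal 1 Mb bins was −0.003 ± 0.108 (SD, n = 10 cells; positive in 6 of 10 cells, exact sign-flip p = 0.932), across bins that are not independent. Shuffled positions gave −0.011 and were called in 6 of 20 shuffles, so this test is slightly off 0 too, and with each cell's shuffled mean subtracted the value was 0.008 (exact sign-flip p = 0.811). With the median position as the centre, the correlation turned to 0.086 (exact sign-flip p = 0.00586), so that gene-dense bins then ranked farther out. Of single megabases, 121 of the 2579 bins located in all cells, or 4.69%, had an exact sign-flip p under 0.05 against the median percentile of 50, about the share that chance gives. No bin passed adjustment over these bins (smallest adjusted exact sign-flip p = 0.812). With 10 cells no single bin can reach a p under 0.00195, so 1 recurring megabase alone could not pass over this many bins.

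None of the 11 gene lists fixed before the data were examined stood apart from all gene-holding bins of the same chromosomes (adjusted p = 0.934 for every list; 0 lists had an unadjusted p under 0.05). Pluripotency regulators, active in these cells, were shifted by −0.50 ± 5.37 points (28 bins, toward the edge in 6 of 10 cells, exact sign-flip p = 0.766). Simulated runs with nothing planted gave this list −1.08 points on average (1 of 20 runs called), and 0.16 with 1 window drawn per bin. Its shift therefore cannot be read against 0. No shuffled values are at hand for the other lists, so whether their shifts are centred on 0 is unknown. Lineage regulators that are silent in embryonic stem cells, such as Hox and Gata genes, were shifted by −2.81 ± 8.68 points (toward the edge in 5 of 10 cells, exact sign-flip p = 0.324). Within batches, this list was at 5.05 ± 3.85 points in B16F (4 of 4 cells toward the edge) and −8.06 ± 6.65 in B18F (5 of 6 cells toward the midpoint), a difference between batches that did not pass adjustment over the lists (exact permutation p = 0.0238, adjusted p = 0.105). With the median position as the centre this list turned to 6.69 points (exact sign-flip p = 0.0117), which did not pass adjustment over the lists either. Imprinted genes were at 1.37 ± 3.03 points (toward the edge in 7 of 10 cells, exact sign-flip p = 0.186). They were at 3.22 points in file 1 alone (unadjusted exact sign-flip p = 0.00781), −0.17 in file 0 alone (exact sign-flip p = 0.926) and 1.57 with single-window percentiles (unadjusted exact sign-flip p = 0.0137), none of which passed adjustment over the lists. Ribosomal protein genes were at −0.32 ± 4.34 (exact sign-flip p = 0.814).

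No list of clustered families passed either. Olfactory receptor genes, 1111 genes in 85 bins, were shifted by 1.11 ± 3.51 points (toward the edge in 7 of 10 cells, exact sign-flip p = 0.346). Vomeronasal receptor genes were at −0.19 ± 4.61 points, histone cluster genes at −1.29 ± 6.93, keratin and keratin-associated genes at −1.85 ± 7.82, and immunoglobulin and T cell receptor genes at −0.25 ± 6.79. With the median position as the centre, olfactory receptor genes turned to −2.95 points (exact sign-flip p = 0.0156) and keratin genes to 5.98 (exact sign-flip p = 0.0215), and immunoglobulin and T cell receptor genes were at −3.65 (exact sign-flip p = 0.0391). None of these passed adjustment over the lists. The protocadherin clusters all lie in 1 bin of chromosome 18 and were at 2.14 ± 22.5 points. Large neuronal adhesion and synapse genes, which are long, were at 0.37 ± 4.86 points, and in 250 kb bins they were farther from the midpoint by 2.80 points (exact sign-flip p = 0.00391), the only list that passed adjustment in any setting.

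**Figure D5:**
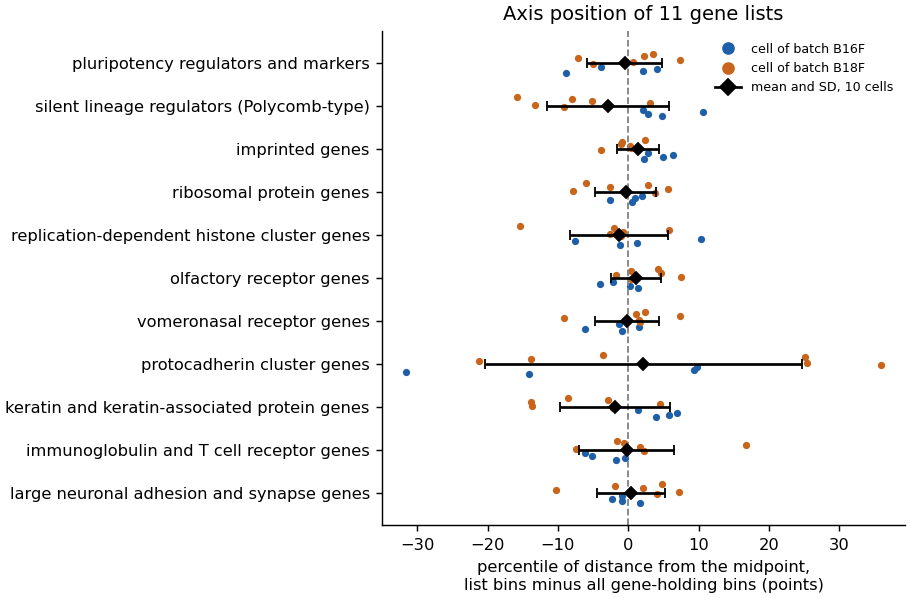
Shift of each of the 11 gene lists from all gene-holding bins of the same chromosomes, in percentile points of distance from the midpoint of the sampled axis, with positive values farther out. Dots are cells coloured by batch, diamonds and bars the mean and SD of 10 cells; every mean lies between −2.81 and 2.14 points and within 1 SD of 0.

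The core pluripotency genes ranged widely from cell to cell. Pou5f1, which encodes the factor Oct4 (chromosome 17, 35506032 to 35510777, mm10), had a mean percentile of 32.8 ± 22.5 over 10 cells, with single cells between 6.61 and 71.1, the lowest mean of its list. Nanog (chromosome 6, 122707489 to 122714633) was at 53.3 ± 27.2, with cells from 14.5 to 96.9. Sox2 (chromosome 3, 34649995 to 34652461) was at 44.3 ± 24.3, Klf4 (chromosome 4, 55527137 to 55532475) at 52.3 ± 23.1 and Zfp42, a stem cell marker also called Rex1 (chromosome 8, 43295067 to 43307009), at 46.0 ± 20.8. Esrrb, a nuclear receptor (chromosome 12, 86361117 to 86521628), had the highest mean of the list at 63.2 ± 21.7, followed by Gbx2 (chromosome 1) at 61.7 ± 22.7, while Tbx3 (chromosome 5) was second lowest at 41.4 ± 20.002. A percentile belongs to the whole 1 Mb bin that holds the gene.

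The extremes of the other lists overlapped in the same way. Among silent regulators, Foxa2 (chromosome 2) was at 34.1 ± 20.6 and Neurog1 (chromosome 13) at 36.7 ± 27.3, against Sox17 (chromosome 1) at 58.9 ± 31.6 and Gata6 (chromosome 18) at 55.3 ± 16.4. Among imprinted genes, Ndn was at 37.4 ± 25.1 and Ube3a, on the same chromosome 7, at 62.96 ± 23.3, while Dlk1 (chromosome 12) was at 43.1 ± 16.04 and Slc38a4 (chromosome 15) at 62.3 ± 20.5. Ribosomal protein genes ran from Rps16 (chromosome 7, 34.9 ± 27.1) and Rpl15 (chromosome 14, 35.0 ± 23.7) to Rpl8 (chromosome 15, 64.5 ± 13.9) and Rps12 (chromosome 10, 66.2 ± 19.8). Olfr155 and Olfr156 share a bin of chromosome 4 at 33.1 ± 15.9, and Olfr1032 and Olfr1033 share a bin of chromosome 2 at 71.4 ± 17.5, the highest mean among the named genes.

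In the remaining families, Vmn2r65 and Vmn2r126 (chromosome 7) were at 39.0 ± 25.3 and 40.3 ± 13.1, against Vmn1r55 (chromosome 7) at 66.5 ± 27.4 and Vmn2r129 (chromosome 4) at 66.98 ± 17.9. H2ac18 and H2ac19 share a bin of chromosome 3 at 35.8 ± 27.9, and H1f5 and H2ac13 a bin of chromosome 13 at 58.3 ± 25.2. Pcdha1 and Pcdha10 (chromosome 18) were at 52.8 ± 27.2. Krtdap (chromosome 7) was at 32.3 ± 20.2, but it matched by its prefix and is neither a keratin nor a keratin-associated protein gene. Krtap28-13 (chromosome 1) was at 38.9 ± 21.4, against Krt1 and Krt2 (chromosome 15) at 57.1 ± 28.2. Igkv1-131 (chromosome 6), which shares its bin and value with another Igkv1 gene named by the same rule, was at 39.2 ± 20.7, Ighv1-85 (chromosome 12) at 57.8 ± 28.8 and Trbv1 (chromosome 6) at 58.4 ± 20.001. Magi2 (chromosome 5, 36.6 ± 22.8) and Cntn4 (chromosome 6, 39.6 ± 32.7) were the lowest of the large neuronal genes, and Opcml (chromosome 9) was among the highest at 64.8 ± 26.97. All these values are means ± SD over 10 cells. The genes are the extremes of their lists, which chance alone spreads apart, and no gene was tested on its own.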

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

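The tests of X blocks, of depth on X, of agreement between the files on X and of the batches within gene lists were chosen after the results were seen; the tests on autosomes and on X minus autosomes without shared windows were written down before their values were computed, but as settings they were chosen after seeing the data. Of 62 groups of 10 cell values searched for a cell far from the others, 8 had such a cell, where chance gives about 1 in 20. Of 35 comparisons between the batches, 4 had an exact permutation p under 0.05, before any adjustment, where chance gives about 1 in 20. The number of profiles per cell, which differed between the batches (exact permutation p = 0.0333), was not counted among the 35.

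The nearly exclusive X windows were weighed first. X windows shared by both files fell under the number for independent files in 10 of 10 cells, and adjacent X windows kept to the same file more often than by chance in all of them, by 36.3 points against 32.4 on the autosomes, so blocks are not particular to X. F123 is a male line as background, so each cell carries a single X. Low depth on X is argued against, since the expectation uses the files' own X windows and the ratio still averaged 0.239. With a single X, the X windows of both files of a cell come from the same copy. File 1 held from 48.3% (Cell39) to 83.1% (Cell19) of a cell's X windows, so neither file was without X in any cell. These values argue against a file number that stands for 1 parental genome along the whole X. Why that copy is written in blocks to either file stays open, because low sharing and blocks are the pattern itself. Y, which a male line also carries once, was not part of that pattern. Its ratio was 0.358 ± 0.578, with Cell20 highest at 1.88, and its same-file excess was 37.1 points. In the mean these values go the same way as on X, but the ratio on Y was not tested and blocks occur on the autosomes too. The design has no group that differs in X, so no biological explanation was tested. Cell20 had a ratio of 0.950, close to that of independent files, against 0.0136 to 0.453 in the other 9 cells. The autosomes of Cell20 had a ratio of 2.50, so its X still shared less than its autosomes. Cell27 (0.453, with a longest run of 1.07 Mb) and Cell39 (0.349) also had higher ratios than the rest.

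The agreement between the files was weighed next. Windows listed by both files were not its whole source, since −0.22 on the log2 scale remained without them, against −0.63 with them. On X, without shared windows, the files placed the same bin at a log2 ratio of −0.49 (below 0 in 9 of 10 cells, exact sign-flip p = 0.00586), as windows of 1 copy written partly to each file would. For pairs of parental copies at the same height, the prediction written down was weaker agreement on X than on autosomes. X minus autosomes was −0.27, with stronger agreement on X in 8 of 10 cells, and missed the threshold (exact sign-flip p = 0.0977). With 1 X per cell, agreement on X compares windows of the same copy. The difference therefore cannot speak for or against pairs of copies on autosomes, and this explanation stays open. What the files stand for is not given in the sources used here, although X argues against 1 parental genome per file (above).

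Other cells far from the rest are given as values. Cell38 had 13.04% of its shared autosomal windows at identical positions, against 38.6% to 66.8% in the others. Cell39 had 54.5% of its adjacent single-file autosomal windows at the same position, against 7.85% to 23.98%, and it has the largest share of windows in 2 positions. Chromosome 8 of Cell26 had 1.21 times the autosomal window density, against 0.835 to 1.02 in the others, and chromosome 12 of Cell39 had 1.73 times, against 0.743 to 1.18. Chromosome 2 of Cell25 had a mean percentile of 61.6 from the midpoint, against 42.7 to 52.6, and chromosome 11 of Cell26 had 33.1, against 46.4 to 60.2. Cell25 had 438 windows on unplaced contigs, against 204 to 327.

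In 3 gene lists the batches had an unadjusted p under 0.05, and none passed adjustment. Silent lineage regulators were at 5.05 percentile points in B16F and −8.06 in B18F (exact permutation p = 0.0238), imprinted genes at 4.10 and −0.45 (exact permutation p = 0.0143) and keratin genes at 4.54 and −6.11 (exact permutation p = 0.0286), and each had an adjusted p of 0.105 over the 11 lists. The correlation of windows per bin with protein-coding genes per bin was 0.012 in B16F and 0.164 in B18F (exact permutation p = 0.0429).

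Unplaced contigs, which entered no position result, held 2769 windows over the 10 cells, with no control files to set them against. In each cell a single file listed them, file 1 in 4 cells (Cell17, Cell18, Cell26 and Cell38) and file 0 in the others, and the same file listed the 2 windows of the mitochondrial genome. The log2 ratio of windows in that file to those in the other file was −0.06 ± 1.06 (SD, n = 10). It was above 0 in 4 of 10 cells (exact sign-flip p = 0.742).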

How the results depend on the processing

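Alternatives named as added (single-window percentiles, shared windows left out, 1 window per bin, shuffled means subtracted) were chosen after seeing the data. The slope on separation (0.013 to 0.063), the contrast of same and different autosomes (0.03 to 0.13) and the agreement of files (−0.78 to −0.16) kept their direction and stayed past the threshold in every alternative that could reach it, including each cell left out, and the 4 cells of B16F alone, which cannot pass, had the same direction. The planned test of neighbouring positions was not run, since a window has 1 position, and lists have no count for B16F alone for lack of cells. With X against each autosome, the difference of 2.70 points turned to −0.70 against chromosome 1 and missed the threshold against chromosomes 2 (2.89), 3 (0.90), 4 (2.36), 5 (2.50), 6 (0.91), 7 (1.93), 10 (2.35), 13 (1.94), 16 (0.36), 18 (0.61) and 19 (4.08), and in B18F alone (1.24). With each cell left out it ranged from 1.997 to 3.22 and passed in 3 of 10 cases. The difference in windows between the files missed the threshold in B18F alone (0.39) and fell from 0.70 to 0.05 in distinct 1 Mb bins, still past the threshold. Single results below are set against an unadjusted p of 0.05 and lists against an adjusted one. Gene-poor minus gene-rich chromosomes passed with 250 kb bins (−1.44), the median as centre (−3.98) and distance scaled to the farthest position (−1.91), and ranged from −2.73 (past the threshold, without Cell38) to −1.60 with each cell left out. Gene density turned to 0.086 with the median as centre. Chromosome length and extent passed without the outermost positions (0.12, exact sign-flip p = 0.0352), nucleolar organisers with file 0 alone (−0.13, exact sign-flip p = 0.0469) and chromosome ends after subtraction of shuffled means (0.22); 1 list passed with 250 kb bins, against 0. With the median as centre, silent lineage regulators (6.69), olfactory receptors (−2.95) and keratins (5.98) turned direction without passing adjustment. So did pluripotency regulators (1.47), ribosomal protein genes (2.55), histone cluster genes (0.75), protocadherin clusters (−0.65) and large neuronal genes (−1.48). Most lists thus changed direction with the choice of centre. The cause was not tested for any of these. The median per cell of 123899 windows became 5260 when distinct 1 Mb bins were counted, since a bin holds many windows. In all, and with those named above that did so, 260 recomputed values kept their side of the threshold. For B16F alone, where no test of the mean can pass, this count takes values within 1 SD of the value for all cells. Among the 260, 24 values in 7 results changed sign without a call. Of 414 recomputed percentiles of named genes, 385 moved by less than 1 SD. The number of windows limits every percentile: a file covers at most 38.1% of the autosomal windows.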

Other observations

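The measure of segregation and both tests of its explanation were chosen after the data were seen, although the correlation of gene count with distance from the midpoint had been computed as set beforehand. Slices of the same nucleus differed in the gene content of the DNA they gave. In Cell26 the mean gene density of a slice ran from 8.18 to 10.9 protein-coding genes per Mb, and in Cell39 from 7.28 to 10.4. Gene counts and axis position were correlated across autosomal bins at 0.218 in Cell26, 0.182 in Cell27 and 0.152 in Cell28, and between −0.0825 and −0.000327 in the other 7 cells.

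Gene-rich and gene-poor megabases of different autosomes kept slightly apart along the axis, most in 3 cells. Distances between the bins with most and with fewest genes exceeded the distances within each of these sets by 0.093 on the log2 scale in Cell26, 0.072 in Cell27 and 0.038 in Cell28. These 3 cells are all of batch B18F and were cut into 8 or fewer profiles. The mean over cells was 0.024 ± 0.033 (SD, n = 10, above 0 in 10 of 10 cells, exact sign-flip p = 0.00195). It was 0.006 in B16F and 0.035 in B18F (exact permutation p = 0.257). Shuffled positions gave 0.00337 on average, from 0.00238 to 0.00445, so this measure cannot be read against 0. Cell17, Cell20 and Cell38 lay under the shuffled mean. With 1 window per bin the mean was 0.00722, above 0 in 10 of 10 cells. That mean rests largely on Cell26 at 0.0328, with the other cells between 0.00119 and 0.0138. No shuffled value is at hand for this setting, so its sign in the cells does not decide whether the sets keep apart. Gene density fell with the number of windows of the slice (mean Spearman correlation −0.302, negative in 8 of 10 cells, exact sign-flip p = 0.0195). Slices of low yield that amplified gene-rich DNA better would give this. Where yield also differs along the axis, gene-rich DNA lying in the slices of low yield would give it too. The correlation cannot tell these apart. Gene-poor DNA at both outer ends of the axis cannot be told apart from no such order, because the mean correlation of −0.00282 misses the threshold and the cells vary in sign. Around the median position the correlation was 0.086 (exact sign-flip p = 0.00586), with gene-dense bins farther out, which goes against this explanation but is measured from another centre than the middle of the axis.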
